A study of Mus musculus with 6 samples.

How the data were processed

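Total RNA of sorted splenic cells from 6 mice, 3 given PBS and 3 given rapamycin, was labelled with biotin in a whole-transcript sense target assay and read on 1 array per mouse, per the labels' protocols. The authors' deposited values are log2 expression values per probe set. Per the submitters' processing notes they were made with RMA in Affymetrix Expression Console, with versions not given in the sources used here. RMA subtracts a background, makes the arrays' value distributions equal and combines the probes of a probe set, so a change of most genes in one direction would be removed. The deposited log2 values ran from 2.71 to 14.2, with nearly equal quartiles on all 6 arrays, and were used without further normalization. Arrays have no sequencing depth, and with 3 arrays per group their number limits the precision. The labels call the mice of a group biological replicates. No 2 arrays shared more than 6.99% of probe set values exactly, so each was counted as a separate sample. The labels used here give no hybridisation or scan date, so array batches were not tested.

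Probe sets were named from GEO's platform annotation of 2016. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed and are unnamed here. Of those with 1 symbol, 21698 were matched by Entrez ID to a RefSeq gene table of the mouse assembly GRCm38, patch 6, and 0 symbols changed. Probe sets with several symbols or none were left out of the comparison. This left 19938 genes, of which 999 had several probe sets. For these the probe set with the highest mean over all 6 arrays was taken. Genes with a mean under the 30th percentile of named probe sets (log2 4.72) were set aside as too dim, which left 13965 and set aside 5973. The genome build behind the array design is not given in the sources used here, so no coordinates are printed.

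Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values, 2-sided, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Standard errors are limma's moderated ones. A total of 35 gene lists was tested with camera, with a preset correlation of 0.01 between members, and Benjamini-Hochberg adjustment over the lists with 5 or more measured members. The lists covered metabolic and growth pathways, immune functions, dissociation stress, the cell types the sort holds and those it could carry over. Of their 956 entries, 867 were matched to a measured gene by symbol or by a synonym that names 1 gene, and 89 were not analysed here. Members under the brightness threshold were left out of the list tests. Of 27 candidate genes fixed in advance, 26 were measured, and 23 lay above the brightness threshold. Ly6c2 shares its probe sets with Ly6c1 and was not analysed here, and Il10, Ido1 and Il6 were tested in the fit of all 19938 genes.

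The genes named in the text were fixed by a rule written before the data were examined, as were the lists, the candidates, the tests and the alternative settings listed here. The rule took the 10 largest and the 10 most negative log2 changes among called genes whose groups do not overlap, passing over predicted genes, small RNAs and segments of antigen receptors. It added the candidates and up to 4 members of each list with the largest moderated statistic. Other members of a list named in the text were chosen after their values were seen. The settings were no or a stricter brightness filter (50th percentile), a repeated quantile normalization, alignment of the array medians and the mean of a gene's probe sets. They also included a test of every probe set, a variance model with intensity trend and robust estimation, limma array weights, an unmoderated fit, the replicate number as a block, and leaving out each array in turn. For lists they were an estimated correlation, fry and members held by 1 list only. A test of the unnamed probe sets in their own fits and a test of symbol families were added after seeing the data.

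The fit was tested on simulated data with the real genes' means and limma's moderated variances. The noise was normal and independent between genes, as the fit assumes, so the test does not cover genes that vary together. At each of several sizes 50 genes were changed, among 13965 genes. The fit recovered 23 of 50 at a log2 change of 0.3, 49 of 50 at 0.6 and 50 of 50 at 1 and at 2, with 12 false among 184 calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.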

Results

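Gene expression was measured on arrays in cells that the labels call splenic myeloid-derived suppressor cells (MDSCs), immature myeloid cells able to restrain T cells. The cells were sorted on CD11b, a surface integrin of neutrophils, monocytes and macrophages, from mice 10 days after allogeneic bone marrow transplantation. The recipients were irradiated B6D2F1 mice, which carry 1 set of chromosomes of the B6 strain, and the marrow, freed of T cells, came from B6 mice. The labels say that B6 spleen cells were or were not added to the graft, without saying for which mice. Mice were injected with rapamycin, an inhibitor of the kinase mTOR, at 1.5 mg/kg or with PBS on alternate days. Each group held 3 mice with 1 array each. The 6 arrays gave values for 35556 probe sets, with medians between 5.42 and 5.46 on the log2 scale. Their number limits the precision of each value below.

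The comparison of rapamycin with PBS asks which genes differed in these cells with mTOR inhibition during the days after the transplantation. Prg4, which encodes the secreted proteoglycan lubricin, was 8.23-fold higher with rapamycin. Rnase2a, a ribonuclease of the eosinophil-associated family, was about 6.41-fold higher from a dim level with PBS, and Mmp12, the macrophage elastase, 5.59-fold higher. Macrod2, a hydrolase of ADP-ribose on proteins, was 2.79-fold lower by the brightest of its 6 probe sets, and 10 of 20 measured genes of cholesterol synthesis fell. Of 13965 genes tested with limma, 617 were higher and 967 lower with rapamycin at an adjusted p under 0.05, which is 11.3% of them. Most changes were small: the called genes that rose had a median log2 change of 0.36, and those that fell one of -0.32. At least 2-fold, 23 genes rose and 11 fell, and at least 1.5-fold, 115 rose and 53 fell. At an unadjusted p under 0.01 and a change of at least 1.5-fold there were 176 genes, 120 of them higher. The 3 arrays of one group all lay above the 3 of the other for 4464 genes (32.0%), where chance gives 10%. The lowest correlation across genes between 2 arrays of a group was 0.9958, and the highest between arrays of different groups was 0.9930. The share of lower genes among the calls was 61.0%, and with the array medians aligned it was 44.7% (875 higher and 707 lower). The count depended on single arrays, in fits that also had fewer samples. Without PBS replicate 2, 52 genes rose and 61 fell. The counts were 164 and 243 without PBS replicate 3, 148 and 220 without rapamycin replicate 1, and 283 and 417 without PBS replicate 1. They were 306 and 406 without rapamycin replicate 2, and 561 and 775 without rapamycin replicate 3. Limma's array weights, estimated over all 6 arrays, were highest for PBS replicate 2 (1.62) and lowest for rapamycin replicate 3 (0.73).

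Among the named genes that rose, Prg4 (probe set 10358476) went from 7.16 ± 0.46 to 10.20 ± 0.44 (log2, mean ± SD, n = 3 each), a log2 change of 3.04 ± 0.28 (SE) with limma's adjusted p of 0.00431. Rnase2a (probe set 10419568) rose by 2.68 ± 0.17 (adjusted p 0.00314 with limma) from a PBS level of 5.13 ± 0.10, under the 50th percentile of probe sets (5.71), so that its fold is approximate, and Mmp12 by 2.48 ± 0.21 (limma adjusted p 0.00380). Alox15, a lipoxygenase that oxidises arachidonic acid, rose by 2.47 ± 0.27, and Saa3, an acute-phase protein, by 2.29 ± 0.26. Ccn3, a matricellular protein, rose by 1.80 ± 0.24, the complement component C4b by 1.57 ± 0.09 and the metal-binding metallothionein Mt2 by 1.56 ± 0.13. Ocstamp, which takes part in the fusion of osteoclast precursors, rose by 1.28 ± 0.19, and the scavenger receptor Cd36 by 1.21 ± 0.25. All 10 were higher in 3 of 3 rapamycin arrays than in any PBS array, which the rule for naming genes required.

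Among the named genes that fell, Macrod2 (probe set 10476590) went from 8.33 ± 0.33 to 6.85 ± 0.20 (log2, mean ± SD, n = 3 each), a log2 change of -1.48 ± 0.17 (SE) with limma's adjusted p of 0.00726. Itih5 (probe set 10469151), a heavy chain of the inter-alpha-trypsin inhibitors, changed by -1.26 ± 0.09 (limma adjusted p 0.00364). The 5 other probe sets of Macrod2 differed by between -0.19 and 0.15, and the mean of all 6 gave -0.28 (adjusted p 0.0180). The immediate early transcription factor Egr1 changed by -1.13 ± 0.17, and Cd101, a surface glycoprotein of mature neutrophils, by -1.12 ± 0.22. Zmpste24, the protease that processes prelamin A, changed by -1.08 ± 0.13, and the adaptor Grap by -1.06 ± 0.11. Hsd17b7, an enzyme of cholesterol synthesis, changed by -1.04 ± 0.11, and the mannose receptor Mrc1 by -1.04 ± 0.14. Asns, which makes asparagine, changed by -1.01 ± 0.12, and the lectin-like receptor Klrb1f went from 9.22 ± 0.03 to 8.22 ± 0.19. Of the 20 named genes, 12 kept their call when any 1 array was left out. Without PBS replicate 2 the adjusted p ran from 0.0504 for Asns to 0.101 for Cd101 in the other 8 (Ccn3, Ocstamp, Cd36, Egr1, Cd101, Zmpste24, Mrc1 and Asns). Ocstamp was also lost without PBS replicate 3 (0.0563), and Ccn3 (0.0506), Egr1 (0.0593) and Mrc1 (0.0527) without rapamycin replicate 1. Cd101 was lost without PBS replicate 1 (0.0812), PBS replicate 3 (0.0891) or rapamycin replicate 1 (0.105), and Cd36 likewise (0.0726, 0.0759 and 0.122) and without rapamycin replicate 3 (0.0730).

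**Figure D1:**
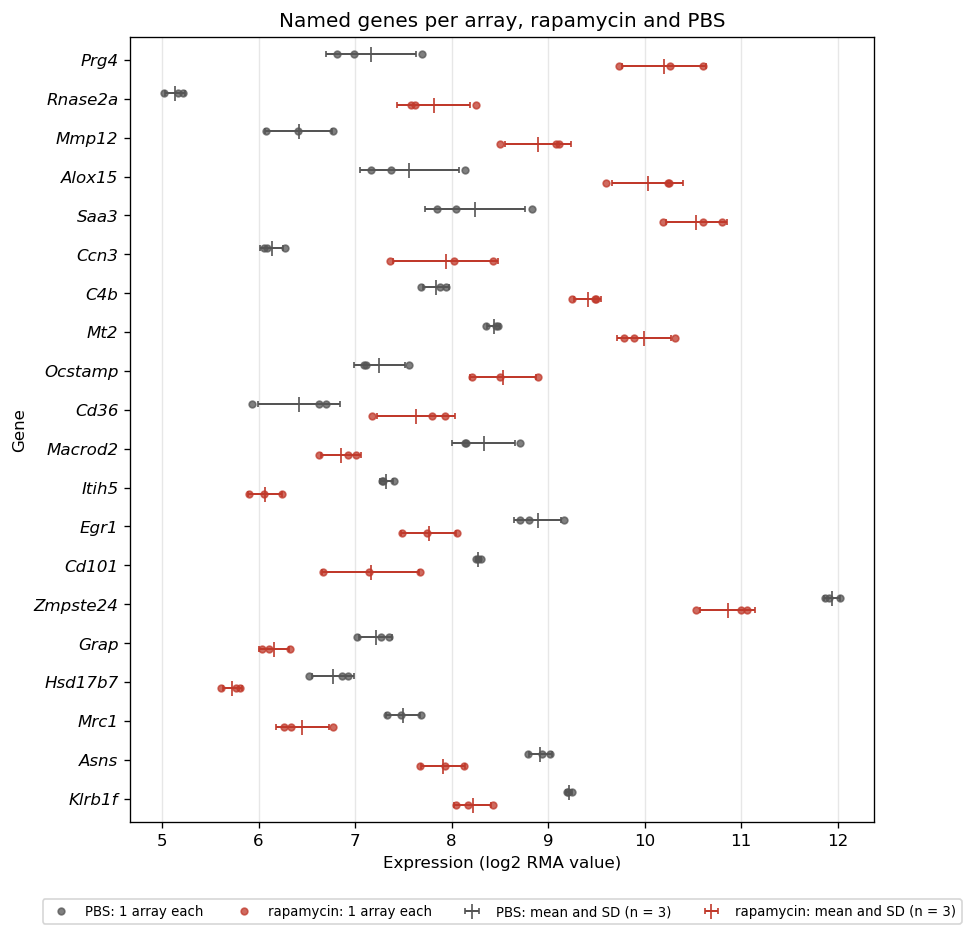
Log2 expression (horizontal axis) of the 20 named genes (vertical axis) on each of 3 PBS and 3 rapamycin arrays. Dots are arrays and bars show the mean ± SD. For every gene the arrays of the 2 groups do not overlap, as the rule for naming genes required, from Prg4 (7.16 against 10.20) to Klrb1f (9.22 against 8.22).

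Of 20 measured genes of cholesterol synthesis, a list that also holds targets of the sterol-sensing factor SREBP2, 10 fell, 0 rose and 10 did not pass the test. Camera called the list lower with rapamycin, at a median log2 change of -0.32 (adjusted p 7.23e-06, and adjusted p = 0.641 with an estimated correlation). When adjusted over the list alone, 12 fell and 1 rose. The count of 10 was 1 (Hsd17b7) without PBS replicate 2, 4 without rapamycin replicate 1, and 6 without PBS replicate 1 or PBS replicate 3. Hsd17b7 showed the largest change, Idi1, an isomerase of the isoprenoid branch, changed by -0.75 ± 0.10 (SE), and Hmgcs1, which makes the precursor of mevalonate, by -0.52 ± 0.07. The sterol sensor Insig1 changed by -0.51 ± 0.08, and Srebf2 itself by -0.21 ± 0.05. In the list of fatty acid synthesis and SREBP1 targets, Elovl6 fell by 0.30 ± 0.05 and the 12 other measured members did not pass the test (camera adjusted p 0.270); Elovl6 kept its call in 1 of the 6 fits with an array left out, that without rapamycin replicate 3.

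Of 51 measured ribosomal protein genes, 21 rose, 0 fell and 30 did not pass the test. Camera called this list higher, at a median of 0.20 (adjusted p 1.63e-16, and adjusted p = 0.641 with an estimated correlation). The counts were 33 higher and 0 lower when adjusted over the list alone. Over all genes tested, 2 rose without PBS replicate 2, 7 without rapamycin replicate 1, 9 without PBS replicate 3, and 10 without PBS replicate 1 or rapamycin replicate 3. Rps3a1 rose by 1.07 ± 0.14 (SE), Rps15a by 0.74 ± 0.06 and Rps12 by 0.63 ± 0.06. Many ribosomal protein genes have near-identical pseudogenes, so their probe sets can hold signal from several loci. Of 25 measured genes of the interferon gamma response and MHC class II, 9 rose and 0 fell, and adjusted over the list alone 19 rose and 0 fell. Of the 9, Irf1 rose by 0.35 ± 0.08 on the brighter of its 2 probe sets and stood at -0.52 ± 0.08 on the other. The mean of both was -0.085 (limma adjusted p 0.501). The T-cell-attracting chemokine Cxcl9 rose by 0.86 ± 0.15, the guanylate-binding protein Gbp5 by 0.80 ± 0.08, the peptide-loading subunit H2-DMa by 0.71 ± 0.14 and the class II chain H2-Eb1 by 0.54 ± 0.11. The median of that list was 0.27 (camera adjusted p 1.35e-08, and adjusted p = 0.641 with an estimated correlation). Its count of 9 was 2 without PBS replicate 2, PBS replicate 3, rapamycin replicate 1 or rapamycin replicate 2, and in each of these fits Cxcl9, H2-DMa and H2-Eb1 were not called. In the list of complement and Fc receptors, properdin (Cfp) rose by 0.38 ± 0.06 and the integrin Itgax by 0.82 ± 0.18, and 15 of 17 measured members did not pass the test. This list was called by camera (adjusted p 0.0210, and adjusted p = 0.641 with an estimated correlation), with 2 members higher when adjusted over the list alone. It was not called without PBS replicate 3 (adjusted p 0.219), after quantile normalization again (0.0660) or with members of 1 list only (0.120, with a median of 0.073 in place of 0.13). Neither Cfp nor Itgax was called without PBS replicate 2 or rapamycin replicate 1, and 1 of them was without PBS replicate 3 or rapamycin replicate 2.

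Of 35 measured genes of the G1/S transition and DNA replication 6 fell, 0 rose and 29 did not pass the test. Camera called this list lower, at a median of -0.10 (adjusted p 0.00633, and adjusted p = 0.641 with an estimated correlation), and the call was lost without PBS replicate 1 (adjusted p 0.0512). When adjusted over the list alone, 8 fell. Over all genes tested, 0 of the members fell without PBS replicate 1, PBS replicate 2, PBS replicate 3 or rapamycin replicate 2, 1 without rapamycin replicate 1 and 3 without rapamycin replicate 3. The largest changes among these were those of the chromatin assembly factor Chaf1a (-0.36 ± 0.07, SE), the primase subunit Prim1 (-0.35 ± 0.07) and the histone mRNA binding protein Slbp (-0.34 ± 0.06). Of 36 measured genes of G2/M and mitosis, Tpx2 fell by 0.22 ± 0.04 and 35 did not pass the test (camera adjusted p 0.386); 0 fell without PBS replicate 2, PBS replicate 3, rapamycin replicate 1 or rapamycin replicate 2, and 3 without rapamycin replicate 3. Of the 35 lists tested, 6 were called by camera with a preset correlation of 0.01 between members, 0 with an estimated correlation and 0 by fry. At an unadjusted p under 0.05, camera gave 13 lists with the preset correlation. The adjusted p of 0.641 with an estimated correlation is a value that the adjustment gives to many lists alike. Unadjusted, camera's p with an estimated correlation was 0.0513 for cholesterol, 0.116 for ribosomal proteins and 0.128 for interferon gamma. It was 0.187 for G1/S, 0.238 for complement and 0.355 for mature neutrophils. The estimated correlation between members was 0.546 for the ribosomal proteins, 0.494 for the interferon gamma list and 0.153 for the cholesterol list, and other splits of the 6 arrays into 3 and 3 gave up to 12 called lists.

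**Figure D2:**
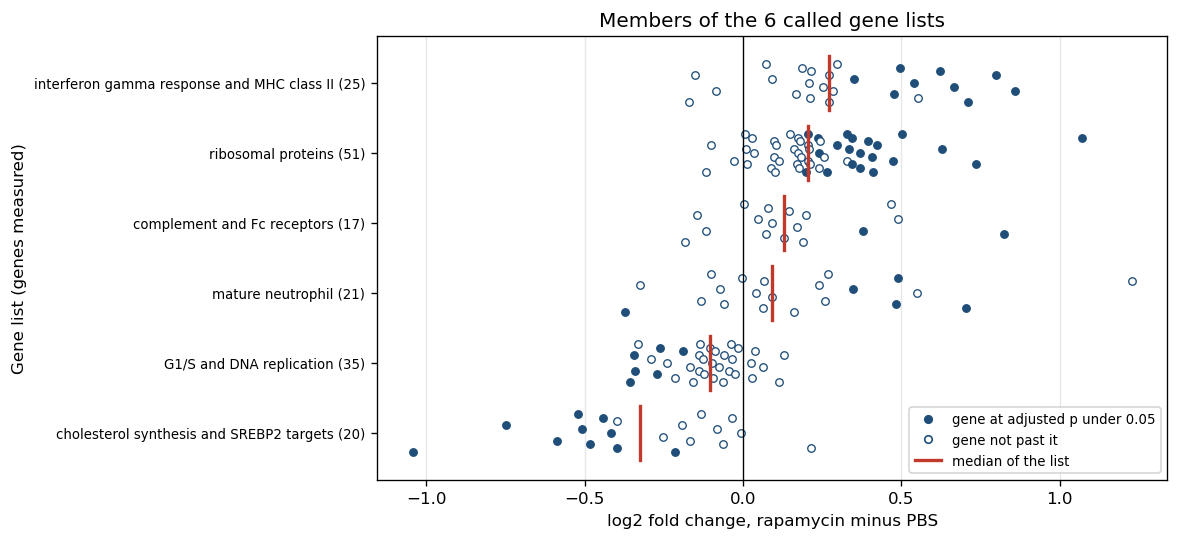
Log2 fold change of rapamycin over PBS (horizontal axis) for the measured members of the 6 lists called by camera (vertical axis, with the number of genes measured). Filled dots are genes at an adjusted p under 0.05, open dots are other genes, and the bar is the median, which runs from -0.32 for cholesterol synthesis to 0.27 for the interferon gamma list.

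Among genes chosen in advance for the function of MDSCs, several with a role in suppression were higher with rapamycin. Hmox1, the stress-induced heme oxygenase, rose by 0.72 ± 0.14 (SE) from 9.69 ± 0.32 to 10.41 ± 0.05 (log2, mean ± SD, n = 3 each). Nos2, the inducible nitric oxide synthase, rose by 0.59 ± 0.12, Il4ra by 0.45 ± 0.06 and Cd274, which encodes the T-cell-inhibiting ligand PD-L1, by 0.37 ± 0.08. Ncf1, a subunit of the NADPH oxidase, changed by -0.24 ± 0.05. Limma's adjusted p was 0.0241 for Hmox1, 0.0272 for Nos2 and Cd274, 0.00855 for Il4ra and 0.0345 for Ncf1. Of 26 candidate genes measured, 4 were higher and 1 lower over all genes, and the counts were the same when adjusted over the list alone. Arg1, which breaks down arginine, varied between mice and gave a log2 change of 0.08 ± 0.43 (adjusted p 0.926 with limma). Ptgs2 differed by 0.54 ± 0.18 (0.0952) and Tgfb1 by 0.20 ± 0.06 (0.0850), neither past the threshold. Ptgs2 was called without rapamycin replicate 3 (0.76, adjusted p 0.0179), with array weights (0.0493) and with the replicate block (0.0471), and Tgfb1 with the array medians aligned (0.0463). The sort marker Itgam (CD11b) differed by -0.12 ± 0.06 and Ly6g, a neutrophil marker, by -0.31 ± 0.14 (limma adjusted p 0.221 and 0.202), and after quantile normalization again Itgam was called at -0.24 (adjusted p 0.0357). The kinase Mtor differed by 0.0039 ± 0.039, and Rptor, Rictor and Fkbp1a, which encodes the protein that binds rapamycin, did not pass the test. Each of the 5 candidate calls was lost without PBS replicate 2, with an adjusted p of 0.0525 for Il4ra, 0.0966 for Nos2, 0.109 for Hmox1, 0.111 for Cd274 and 0.118 for Ncf1. The candidates called numbered 2 without PBS replicate 1, 1 without PBS replicate 3 and 1 without rapamycin replicate 1. In the wider list of MDSC effectors, 6 of 27 measured genes rose and 1 fell, among them the ectonucleotidase Entpd1 (0.36 ± 0.08) and the arginine transporter Slc7a2 (0.70 ± 0.17). The list was not called by camera (adjusted p 0.165), except as higher without rapamycin replicate 3 (0.0282), and 9 rose and 4 fell when adjusted over the list alone. Its 7 calls became 0 without PBS replicate 2, 1 without PBS replicate 3 or rapamycin replicate 1, 2 without PBS replicate 1 and 4 without rapamycin replicate 2.

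**Figure D3:**
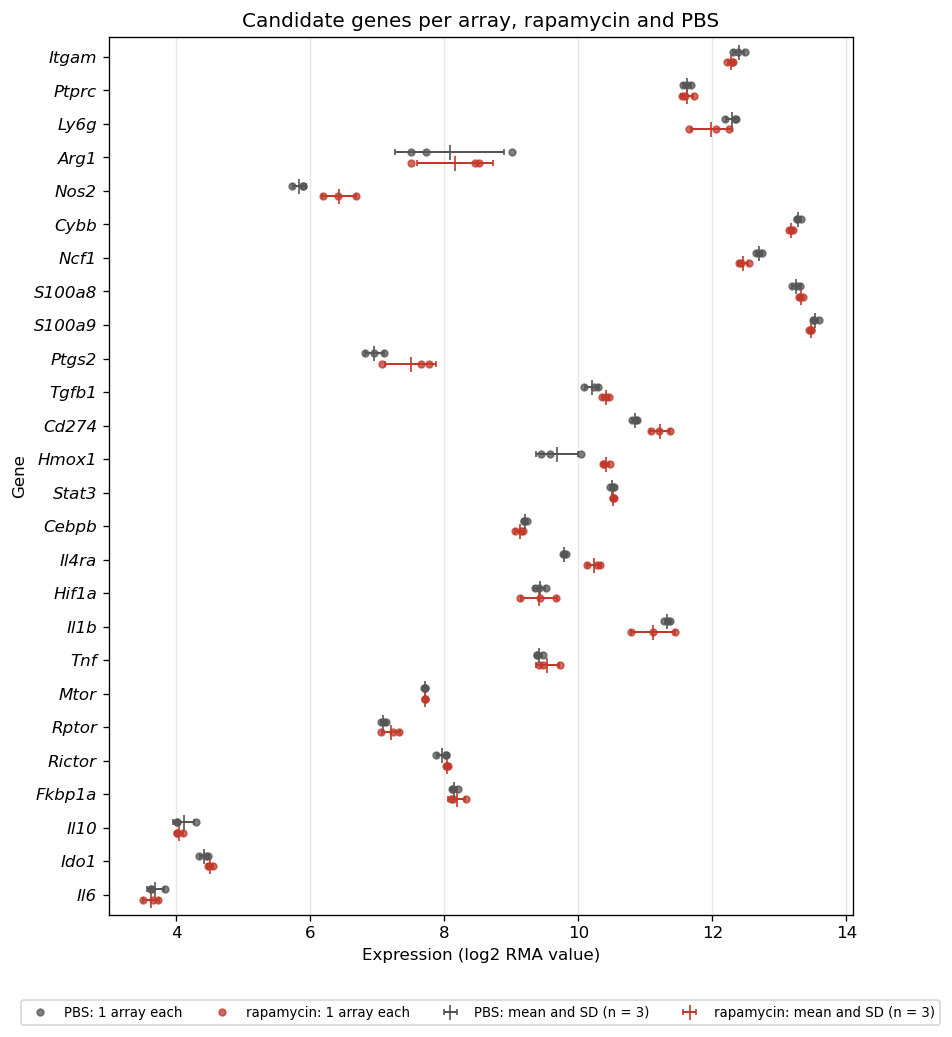
Log2 expression (horizontal axis) of the 26 measured candidate genes (vertical axis) on each of 3 PBS and 3 rapamycin arrays. Dots are arrays and bars show the mean ± SD; Hmox1 lies at 9.69 with PBS and 10.41 with rapamycin, while the Arg1 arrays of the 2 groups overlap.

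Markers of the cell types that the CD11b sort holds moved in both directions. Of 21 measured genes of mature neutrophils 4 rose and 1 fell: the decoy receptor Il1r2 rose by 0.70 ± 0.07 (SE), Il1f9 by 0.49 ± 0.09, the protease inhibitor Slpi by 0.48 ± 0.07 and the receptor Trem1 by 0.35 ± 0.09, and the transcription factor Mxd1 changed by -0.37 ± 0.08. Adjusted over the list alone, 5 rose and 1 fell. Camera called this list (adjusted p 0.0318, and adjusted p = 0.646 with an estimated correlation). It was not called without PBS replicate 1 (adjusted p 0.0808), PBS replicate 3 (0.133), rapamycin replicate 1 (0.0548) or rapamycin replicate 2 (0.112), nor with the array medians aligned (0.0530) or after quantile normalization again (0.0656). Of 21 measured macrophage genes 4 rose and 2 fell, with Cd68 0.83 ± 0.09 higher, the iron carrier Trf 0.69 ± 0.10 higher and the iron exporter Slc40a1 at -0.38 ± 0.05 (camera adjusted p 0.0718). Camera called this list higher without PBS replicate 1 (adjusted p 0.00268), PBS replicate 2 (0.0440) or rapamycin replicate 1 (0.0469), with the replicate block (0.0352) and after quantile normalization again (0.0324). These calls used the preset correlation, and with an estimated one over all 6 arrays camera's adjusted p was 0.646. Monocyte genes split evenly, 3 higher and 3 lower of 24 (camera adjusted p 0.740): Tmem176b and Ms4a6c rose, and Ace, Cd300e and Ccr2 fell. Of 20 dendritic cell genes 1 rose and 1 fell (0.316), and of 25 genes of neutrophil secondary granules 1 fell (0.606). Of 18 genes of primary granules and neutrophil progenitors 1 rose and 2 fell (0.971). Of 7 measured eosinophil genes, Alox15 rose and the others, Siglecf and Ccr3 among them, did not pass the test. Their median was 0.031 and their mean 0.38 (camera adjusted p 0.173). Adjusted over the list alone, 6 macrophage genes rose and 2 fell, 6 monocyte genes rose and 7 fell, and 3 dendritic cell genes rose and 2 fell. None of 11 genes of basophils and mast cells passed the test (0.370), and adjusted over the list alone 3 fell. The 24 genes called over these 8 lists became 3 without PBS replicate 2, 7 without PBS replicate 3, 8 without rapamycin replicate 1 and 13 without rapamycin replicate 2. Without rapamycin replicate 3 they became 29, with 8 mature neutrophil genes called, 7 of them higher, and with 1 gene of basophils and mast cells higher and 3 lower.

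Markers of lymphocytes that a bead sort can carry over were lower in part. Of 19 measured T cell genes 3 fell and 0 rose: Ubash3a changed by -0.51 ± 0.10 (SE), Cd3g by -0.39 ± 0.09 and Cd8a by -0.27 ± 0.06. Of 10 measured genes of NK and cytotoxic lymphocytes, Gzmb (-0.76 ± 0.11), Nkg7 (-0.66 ± 0.12) and Il2rb (-0.43 ± 0.07) fell. The counts were 4 lower T cell genes, and 4 lower and 1 higher cytotoxic genes, when adjusted over the list alone. The lists themselves were not called by camera (adjusted p 0.0856 for T cells and 0.0847 for cytotoxic lymphocytes), though without a brightness filter that of T cells was called lower (0.0209). Of 10 B cell genes Cd37 rose and Cd79b fell (0.740), and of 17 erythroid genes Slc4a1 rose by 0.64 ± 0.09 (0.141). Of 14 platelet genes Itgb3 fell (0.664), and of 15 genes of stem and progenitor cells Lmo2 fell by 0.51 ± 0.05 (0.259). Adjusted over the list alone these counts were the same, except for 2 lower platelet genes. None of 15 plasma cell genes (camera adjusted p 0.386) and none of 19 genes of stroma and endothelium (0.370) passed the limma test. Without PBS replicate 2 or PBS replicate 3 no T cell or cytotoxic gene was called, and without rapamycin replicate 1 or rapamycin replicate 2 no T cell gene. Over the lists of this kind 11 of 118 measured genes were called, against 11.3% of all genes tested. The 11 became 2 without PBS replicate 2, 3 without PBS replicate 3 and 6 without rapamycin replicate 1.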

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

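The tests of the unnamed probe sets were chosen after the results of the comparison were seen. A signal between the groups appeared in probe sets that the comparison did not use. Of 6617 unnamed probe sets numbered before the first annotated one, 538 were called by limma in a fit of their own, 376 higher and 162 lower with rapamycin. Of the 5529 other unnamed probe sets 442 were called, 296 higher and 146 lower. The shares called were 8.13% and 7.99%, against 11.3% of the named genes that passed the brightness filter. No such filter was put on the unnamed probe sets. Without it 489 of 19938 genes were higher and 772 lower, a smaller share than of either kind of unnamed probe set. At a change of 2-fold or more, 186 probe sets of the first range were called, against 34 of the filtered genes. The log2 changes of all 6617 ran from -4.18 to 2.76 and had an SD of 0.41, against 0.19 for the filtered genes. The median SD within groups was 0.205 against 0.077. The first range is taken here as that of the array's control probe sets, which no source used here states. In each of the other 9 splits of the 6 arrays into 3 and 3, 0 probe sets of either kind were called.

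The pattern weighed here is the number of genes called between rapamycin and PBS, with an effect of the treatment set against a technical difference between the groups' arrays. If the arrays of the groups had been labelled or hybridised apart, probe sets of the range taken as controls could be called in the real split well above the other splits, and 538 against a highest other count of 0 met that prediction. The count of 0 carries little weight, since any difference between the groups widens the spread within the other splits. The test does not separate the explanations either. A treatment effect on transcripts that these probe sets read would give the same, and what they read is not known here. A batch that follows the groups and the treatment therefore cannot be told apart, for want of hybridisation dates in the labels used here. Nor can added spleen cells be told apart from the treatment, since the labels do not say which mice received them. For the genes themselves, 1 of the 10 splits gave as many calls, the real one with 1584 genes. The highest other split gave 0, with the same limit, and 10 splits are too few for a share under 0.05.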

How the results depend on the processing

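None of the 1584 called genes changed sign under any alternative in which the same genes were tested, except 4 with the mean of a gene's probe sets. For several alternatives this was fixed in advance. The filters, the trended variance, the unmoderated fit and the replicate block leave a gene's log2 change as it is. A gene whose groups do not overlap cannot change sign when 1 array is left out. Filters, scaling, array weights, the trended variance and the mean of probe sets gave between 489 and 875 higher genes and between 707 and 1342 lower ones, and between 1219 and 1561 of the 1584 stayed called. Testing every probe set gave 824 higher and 1103 lower probe sets. The unmoderated fit, which has 4 residual degrees of freedom per gene, gave 29 higher and 57 lower genes (83 of them shared), 106 genes at an unadjusted p under 0.01 and 1.5-fold, and 0 called candidates. Leaving out 1 array in turn, with fewer samples in each fit, gave from 52 (without PBS replicate 2) to 561 higher genes (without rapamycin replicate 3), from 61 to 775 lower genes, from 0 to 4 called candidates and from 4 (without PBS replicate 3) to 10 called lists (without rapamycin replicate 3). With an estimated correlation 0 lists were called, and with fry, which does not compare a list with other genes, 0 by direction and 31 by change in either direction. Over all alternatives the adjusted p ran from 3.53e-07 to 0.641 for the cholesterol list, 9.99e-24 to 0.641 for the ribosomal proteins, 1.46e-11 to 0.641 for the interferon gamma list, 0.000497 to 0.641 for G1/S, 0.00239 to 0.641 for complement and 0.000519 to 0.646 for mature neutrophils. For the 20 named genes it reached at most 0.161 (Cd36), and for the 5 called candidates at most 0.151 (Nos2). The array medians over the kept genes lay between 6.73 and 6.80, and no scaling moved the median of all genes by over 0.1. Signal near the background limits dim genes, and 5973 were not in the comparison.

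Among called genes that the rule names or a list holds, the call was kept in 1718 pairs of gene and alternative and lost in the same direction in 708. Of these Irf1 turned, from 0.35 to -0.085 with the mean of its probe sets. The other changes of direction were of genes and lists not past the threshold, and the cause was not tested. After quantile normalization again, Ptprc stood at -0.091 and Stat3 at -0.044. With array weights, Ptprc stood at -0.0069, Arg1 at -0.16 and Hif1a at 0.012, and with aligned medians Hif1a stood at 0.020. Leaving out 1 array gave Arg1 between -0.21 and 0.55, Hif1a between -0.14 and 0.13, Ptprc between -0.053 and 0.038, Fkbp1a between -0.036 and 0.078 and Ccr3 between -0.00034 and 0.11. For lists the direction is that of the test, which can differ from the sign of the median given here. The glycolysis list turned without a filter (-0.0076), after quantile normalization again (-0.035), with aligned medians (0.024), with the mean of probe sets (6.5e-05) and with fry (-0.0076). With fry the chemokine list (0.029) and the monocyte list (-0.016) turned too. A stricter filter turned the lists of primary granules (-0.030) and stroma (-0.052), and members of 1 list only those of primary granules (-0.0021) and B cells (-0.11). Leaving out 1 array gave medians between -0.023 and 0.042 for glycolysis, -0.020 and 0.039 for G2/M, -0.051 and 0.14 for type I interferon, and -0.087 and -0.033 for immediate early genes. The ranges were -0.057 to -0.021 for primary granules, -0.081 to -0.010 for secondary granules, -0.071 to 0.037 for monocytes, -0.070 to 0.0083 for B cells and -0.059 to -0.0069 for platelets.

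The replicate numbers were also used as a block. Arrays of the same number deviated together with correlations of 0.263, 0.00995 and 0.0456 across genes. The first was the highest of all pairs, and pairs of different numbers ran from -0.193 to 0.138. Not every array correlated best with its own number, so these values neither show nor exclude a pairing by number. With the replicate block, 768 genes were higher and 923 lower (1338 shared), 185 passed an unadjusted p under 0.01 at 1.5-fold, 6 candidates were called, and 8 lists were called, the 6 called without it among them.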

Other observations

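Genes of energy metabolism and nutrient sensing moved in both directions with rapamycin, and none of their lists was called by camera over all 6 arrays with the settings of the comparison. The list of ribosome biogenesis and MYC targets was called higher in 6 of 16 other settings (adjusted p down to 0.00504, without PBS replicate 1), that of oxidative phosphorylation in 2 (0.0190 without rapamycin replicate 2, 0.0463 without PBS replicate 2) and that of lysosome and autophagy in 1 (0.0162, without rapamycin replicate 2). With an estimated correlation over all 6 arrays camera's adjusted p was 0.646 for the first list and 0.641 for each of the others. Among 19 glycolysis genes, Ldha changed by -0.46 ± 0.05 (log2, SE), Hk2 by -0.43 ± 0.05 and Pgam1 by -0.24 ± 0.06, while Hk1 rose by 0.34 ± 0.08 on the brighter of its 2 probe sets and stood at -0.32 ± 0.05 on the other (mean 0.0071, adjusted p 0.942; camera adjusted p 0.917, with a direction that depends on the scaling). Adjusted over the list alone, 4 fell and 1 rose. Of 19 genes of the hypoxia response 4 rose and 3 fell, with Ankrd37 0.48 ± 0.12 higher and the mitophagy receptor Bnip3l at -0.43 ± 0.07 (camera adjusted p 0.214). Of 48 genes of oxidative phosphorylation 6 rose and 2 fell; Cox4i1 rose by 0.44 ± 0.06 and Sdhc by 0.44 ± 0.06, and Ndufs1 changed by -0.28 ± 0.05 (camera adjusted p 0.0718). Of 21 genes of the amino acid response, the cystine transporter Slc7a11 rose by 0.74 ± 0.09, and Atf4 itself by 0.22 ± 0.04, while Asns and Psat1 fell (camera adjusted p 0.561). Of 34 lysosome and autophagy genes the cathepsins Ctsd (0.47 ± 0.06) and Ctsa (0.36 ± 0.06) rose, and Wipi1, Becn1 and Fnip1 fell (camera adjusted p 0.0847). Of 30 genes of ribosome biogenesis and MYC targets, Myc rose by 0.71 ± 0.13 and Odc1 by 0.36 ± 0.07 (0.064 on its other probe set, and 0.21 with adjusted p 0.107 for the mean of both), and Polr1a changed by -0.35 ± 0.04 (camera adjusted p 0.0718). Adjusted over the list alone, 5 hypoxia genes rose and 4 fell, and the counts of the other 4 lists were the same as over all genes. The 33 genes called over these 6 lists became 2 without PBS replicate 2, 11 without PBS replicate 3 or rapamycin replicate 1, 16 without PBS replicate 1 and 17 without rapamycin replicate 2. Hk1 was not called after quantile normalization again (0.21, adjusted p 0.0818) or with any 1 array left out.

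Inflammatory and stress genes were mixed as well over all 6 arrays. Of 23 immediate early and dissociation stress genes 5 fell, with Ier2 at -0.55 ± 0.08, Junb at -0.46 ± 0.09 and Klf2 at -0.44 ± 0.08 besides Egr1, and 3 rose, with Atf3 at 0.55 ± 0.07 (camera adjusted p 0.733). Of 23 inflammatory cytokines and NF-kB targets Il27 rose by 0.48 ± 0.10, and Nfkbia and Ccl3 fell (camera adjusted p 0.0847); adjusted over the list alone, 8 rose and 3 fell. Of 19 chemokines and receptors 2 fell (camera adjusted p 0.692), and of 26 genes of the type I interferon response Oas2 and Usp18 rose and Bst2 fell (camera adjusted p 0.251). Of 18 genes of alternative macrophage activation Retnla rose by 0.58 ± 0.13 and Socs2 by 0.31 ± 0.06 (0.18 as the mean of its 2 probe sets, adjusted p 0.0474), as did Il4ra, and Mrc1 fell (camera adjusted p 0.251). When adjusted over the list alone, 6 immediate early genes rose and 6 fell, 1 chemokine gene rose and 4 fell, 3 type I interferon genes rose and 1 fell, and 4 genes of alternative activation rose and 2 fell. The 19 genes called over these 5 lists became 1 without PBS replicate 2, 4 without rapamycin replicate 1, 5 without PBS replicate 3, 9 without PBS replicate 1 and 11 without rapamycin replicate 2. Without rapamycin replicate 3 they became 28, with 20 higher in place of 9 and 8 lower in place of 10, among them 6 higher type I interferon genes, 5 higher inflammatory genes and 3 higher chemokine genes. In that fit camera called the type I interferon list (adjusted p 0.000906) and the inflammatory list (0.00704) higher, and the inflammatory list also with members of 1 list only (0.0369). These calls used the preset correlation. With an estimated one over all 6 arrays camera's adjusted p was 0.885 for the type I interferon list and 0.646 for the inflammatory list. Among 172 symbol families tested for called genes after the data were seen (344 Fisher's exact tests), Snora held 9 higher genes of 19 (adjusted p 6.46e-06), Rps 12 of 30 (7.13e-07), Rpl 9 of 35 (0.00174) and Cd 12 of 70 (0.00434), and no other family passed. Fisher's test takes genes as independent, and the ribosomal protein list, with an estimated correlation of 0.546 between members, had adjusted p = 0.641 by camera with that correlation, so these p are too small where family members vary together.

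The tests of symbol families above and of recipient cells, random lists, marker brightness, dividing cells and single lists in other splits below were chosen after the results were seen. The marker lists of peritoneal macrophages and eosinophils were written after the pattern and before their test. The joint rise of Prg4, Rnase2a, Mmp12, Alox15 and Saa3 was set against other cells in the sort, since CD11b beads also hold eosinophils and macrophages. More eosinophils would raise their other markers, but 3 of the 9 genes listed for them lay above the stricter brightness threshold (log2 5.71). The median of the 9, 0.014 (95% bootstrap interval over genes -0.046 to 0.091), thus decides nothing. Of the 3, Siglecf stood at 0.031 ± 0.037 (SE) and Ear6 at -0.020 ± 0.42. Ccl11, which encodes a chemokine that attracts eosinophils and is not a marker of the cells themselves, stood at 0.13 ± 0.066. More recipient cells would raise genes of the recipient's own alleles: H2-Ea, a class II chain that B6 cells lack, differed by 0.095 (95% confidence interval -0.071 to 0.26) at a mean of 5.18, under that threshold, while of 2 other markers chosen for this Nnt fell by 0.25 ± 0.044 (limma adjusted p 0.0226) and Gbp2b stood at -0.046 ± 0.15, both with a high baseline (8.40 and 7.98), so recipient cells stay open. Large peritoneal macrophages carried over remain a candidate source: 18 of their markers had a median of 0.24 (95% bootstrap interval over markers 0.041 to 0.44), 14 of them positive and 4 negative. F10, Ltbp1, Cd93, Gata6 and Tgfb2 passed the threshold in the comparison, and F10 and Ltbp1 also in the fit of all 19938 genes. The other 3 had limma adjusted p between 0.0506 and 0.0710 there. Of the called markers, Gata6 (mean 5.41) and Tgfb2 (4.86) lay under the stricter brightness threshold. So did Cxcl13 (1.145, 95% confidence interval -0.11 to 2.40), which was not called, and Vsig4 (0.32) and Rarb (-0.034), which were too dim for the comparison. The 13 markers above that threshold had a median of 0.24. Timd4 (0.71, 95% confidence interval 0.23 to 1.18), Itga6 (0.46, 0.12 to 0.80), Icam2 (0.25, 0.076 to 0.42) and Garnl3 (0.24, 0.032 to 0.45) were higher but not called. The abundant Fn1 (0.066), Lrg1 (0.034), Emilin2 (0.048), F5 (-0.095), Thbs1 (-0.28) and Cd9 (-0.37, -0.61 to -0.14) were not called either. The markers thus moved in both directions and decide neither way. An effect of rapamycin on splenic macrophages stays open too, with 10 markers of red pulp macrophages at a median of 0.17 (-0.12 to 0.49).

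The fall of the cholesterol synthesis genes was set against a random shift of genes of like brightness and against fewer dividing cells. Of 10000 random lists of 20 genes matched on mean expression, 0 had a median as low as -0.32, and the lowest was -0.19. Genes drawn at random do not vary together as the members of this list do (estimated correlation 0.153). The draws thus do not show how far such a list moves between mice. For the ribosomal protein and interferon gamma lists too, 0 of 10000 random lists had a median as high. The mitotic genes had a median of 0.027 (95% bootstrap interval -0.035 to 0.044), and the G1/S and DNA replication genes, 6 of 35 of them lower, one of -0.10 (-0.16 to -0.063; camera adjusted p 0.00633, and adjusted p = 0.641 with an estimated correlation). These intervals resample genes and not mice, so they do not measure the spread between mice. Over all alternative settings, those with 1 array left out among them, the cholesterol median ran from -0.40 to -0.25. The mitotic median ran from -0.020 to 0.059 and that of G1/S from -0.12 to -0.072. Both lie above the fall, which argues against fewer dividing cells as its whole source, though not as part of it. An effect of the treatment and a batch that follows the groups stay open, and arrays of both groups hybridised in 1 batch would be needed to tell these apart. A difference between the groups in added spleen cells, which the labels assign to no mouse, stays open too. So does a change in the mix of sorted cells other than dividing ones, which was not tested for this list.

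For the lists, 7 of the 10 splits of the 6 arrays, the real one included, gave 6 or more calls by camera, and the highest other split gave 12; 10 splits are too few for a share under 0.05. Each of the 9 other splits sets 2 arrays of a group and 1 of the other against the rest, so part of the treatment difference stays in it. The cholesterol list was called in 4 of them with a largest absolute median of 0.18, the ribosomal proteins in 5 (0.15) and the interferon gamma list in 5 (0.26). The real split gave medians of -0.32, 0.20 and 0.27. Camera's lowest adjusted p in the other splits was 4.43e-06, 1.18e-16 and 6.19e-11, below 7.23e-06, 1.63e-16 and 1.35e-08 in the real one. For mature neutrophils another split gave a larger absolute median, 0.17 against 0.092 in the real one. For G1/S (0.076 against -0.10) and complement (0.11 against 0.13) the real median was the larger in size. Whether the calls in the other splits come from that remainder or from differences between mice or arrays was not separated.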
